A study of Mus musculus with 16 samples.

How the data were processed

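The series covers RNA-seq of mouse embryonic stem cells, wild-type E14 and Suz12 knock-out, cultured without LIF in 1 uM all-trans retinoic acid for 0, 24, 48 or 72 h, with 16 samples in 8 groups of 2 by the labels. Total RNA was depleted of ribosomal RNA before sequencing. The submitters' processing notes name TopHat, featureCounts and DESeq2 and the GRCm38 (mm10) genome, without versions. The values analysed are those of the deposited table, in which the authors give RPKM (read numbers scaled to gene length and library size) for 24452 genes identified by Ensembl release 72 gene IDs, with 1 column for each of the 8 groups. The deposited table also holds TRUE or FALSE marks by the authors for genes that differ between 72 and 0 h in WT and in Suz12-KO cells. The marks give no direction, and directions were taken here from the change in scaled RPKM unless another scale is named. Their threshold is not given in the sources used here. How the replicates were pooled into a column is also not given.

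Whole read numbers were recovered from the RPKM values by finding for each column the total, and for each gene the length, that turned every value into a whole number of reads. All 153803 values above 0 came out whole within 0.01 reads, using the annotated exon length for 13714 genes and a length found from the steps between values for 10738 genes. The totals were 25824216, 28027373, 24731176 and 26430463 reads for WT cells at 0, 24, 48 and 72 h and 27205523, 26390381, 32153765 and 25277999 reads for Suz12-KO cells. Read numbers were used for exact Poisson 95% intervals, for the upper limit that a count of 0 allows (3 reads), for simulations and for sums of reads over columns, and never as input to limma or the list tests. Intervals and limits cover counting error only. Symbols, classes and positions came from GENCODE M21 (GRCm38), matched by gene ID, and 595 genes had no current symbol.

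The tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. That plan was a limma fit to 16 libraries with RPKM as deposited. The table holds 1 pooled column per group, so those tests, which need replicates within a group, were not run for single times, for time courses or for the differences between responses, and trends over time were not fitted in their place. These comparisons are given as values, as counts of genes at least 2-fold apart and beside the authors' marks, without p values. "Rose" and "fell" are used for changes over time in genes that carry the authors' mark and "higher" or "lower" elsewhere. Genes were kept with at least 1 RPKM in at least 1 of the 8 columns (10860 genes), in place of the planned 2 of 16 libraries. Values were log2(RPKM + 0.5). Because a few abundant RNAs took different shares of the reads, the scaling factors ran from -0.53 (WT at 0 h) to 0.26 (Suz12-KO at 48 h) on the log2 scale, and RPKM were divided by a median-of-ratios factor per column for all comparisons of single columns. This choice was made after the data were seen, and the total counts of genes at least 2-fold apart as deposited are given beside it. Genes at 0 or with few reads in a column have log2 changes that depend on the added 0.5. For each pair of columns the number of 2-fold differences expected from counting error alone was simulated by drawing both columns from 1 shared rate.

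The Suz12-KO minus WT difference averaged over time was tested with limma 3.58.1 (R 4.3.3), with trended empirical Bayes, on log2(RPKM + 0.5) as deposited, with time as a block (3 residual degrees of freedom), and Benjamini-Hochberg adjustment at 0.05. This fit to 8 columns replaced the planned fit to 16 libraries. Each line gives 1 column per time, so the test measures how a difference varies over time. On simulated data with 200 changed genes of 10860, it recovered 76% of 2-fold and 92% of 4-fold changes, and 6.67% of its calls were false. All other simulated genes had no difference between the lines, whereas the median gene as deposited differed by 0.15. The false share therefore does not describe the real calls. Gene lists with at least 5 measured genes were tested with camera (preset correlation 0.01), with camera at an estimated correlation and, on scaled RPKM, with fry. For single comparisons a list's median was set against 10000 random lists matched on expression in 20 bins. Random members were drawn independently, so these ranges ignore correlation between the genes of a list and are too narrow where it is high. They were not adjusted for the number of lists and comparisons. In a check on 40 simulated lists of 20 genes, 2 unchanged lists fell outside the middle 95% and 40 lists shifted by 1 log2 unit fell above it.

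The 26 lists were PRC2 subunits, PRC1 subunits, H3K27 and H3K4 enzymes, DNA methylation enzymes, the pluripotency network, formative and primed markers, retinoic acid response, Hox genes, developmental transcription factors, endoderm, mesoderm, neural, trophoblast and fibroblast markers, blood and endothelial markers, epithelial and adhesion genes, germline genes, 2-cell-like genes, imprinted genes, p53 targets, cell-cycle inhibitors, replication genes, mitosis genes, housekeeping genes, abundant structural RNAs, and X and Y line markers. The X and Y list and the blood and endothelial list had fewer than 5 measured genes and gave no result. Named genes are, for each of 5 main comparisons, the 8 with the largest change in either direction among those with at least 5 RPKM in a compared column and a change beyond counting error (or the authors' mark), the 3 members of each list with the smallest p in the averaged test, and 16 fixed genes. In the plan the first part had asked for an adjusted p and separate replicates. Under that part, genes with the usual symbols of microRNA, small RNA and predicted genes (such as Mir, Snor, Gm or Rik) were counted and not named. Short RNA genes with other symbols, such as DQ267102 and Vaultrc5, were named. Of the fixed genes, Cdx2, T and Xist stayed under 1 RPKM in every column.

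Alternatives were pseudocounts of 0.1 and 1, no filter, a minimum of 5 RPKM, median-of-ratios scaling or RPKM as deposited, quantile normalization, robust empirical Bayes, a fold minimum, and a set of silenced or induced genes chosen on Suz12-KO cells. Protein-coding genes alone, RPKM as deposited for single columns and leaving out both columns of each time were added after the data were seen. Other computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.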

Results

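RNA was sequenced from mouse embryonic stem cells while they differentiated in retinoic acid, a vitamin A derivative that drives these cells out of pluripotency. Wild-type E14 cells (WT) and a line labelled Suz12 knock-out (Suz12-KO) were sampled before treatment (0 h) and at 24, 48 and 72 h. Suz12 is a core subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3 at lysine 27 over silent genes. The labels give 16 samples in 8 groups of 2 replicates, and the deposited table gives 1 RPKM column per group for 24452 genes. No spread between replicate cultures could therefore be computed for any value. Bracketed intervals of RPKM are 95% Poisson intervals that cover counting error only. The reads behind each column numbered from 24731176 (WT at 48 h) to 32153765 (Suz12-KO at 48 h). One annotated non-coding gene, Gm42418, took 65.5% of the reads in WT cells at 0 h and 56.6% in Suz12-KO cells at 72 h. Whether these reads come from a transcript of that gene was not tested. Protein-coding genes took 5433019 of 25824216 reads at 0 h and 27.8% of the reads at 72 h in WT cells, and 23.1% and 30.7% in Suz12-KO cells. Within these shares Lars2 alone took 1380006 reads in WT cells at 0 h and 5.6% of all reads in Suz12-KO cells at 72 h. The median gene moved with these shares, so single-time changes below are log2 differences of RPKM after scaling to that median, and printed RPKM values are as deposited. The shift removed was 0.27, 0.30, 0.18 and 0.06 on the log2 scale for Suz12-KO minus WT at 0, 24, 48 and 72 h. For 72 h minus 0 h it was 0.63 in WT cells and 0.42 in Suz12-KO cells.

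The targeted gene itself was examined first, as a check of the labels. Suz12 (ENSMUSG00000017548, chromosome 11, 79993106 to 80034123 in GRCm38) was read in every column of both lines. In WT cells it stood at 2.94 RPKM (2.65 to 3.25) at 0 h, 2.58 at 24 h, 1.26 at 48 h and 0.995 (0.831 to 1.18) at 72 h. In the columns labelled Suz12-KO it stood at 2.59 RPKM (2.33 to 2.88) at 0 h, 3.09 at 24 h, 2.38 at 48 h and 1.35 (1.16 to 1.57) at 72 h. Averaged over the 4 times, Suz12-KO minus WT was 0.27 (SE 0.14, limma adjusted p = 0.246), and Suz12-KO cells were higher at 3 of 4 times on the deposited scale. After scaling the averaged difference was 0.10 (adjusted p = 0.753), from -0.39 at 0 h, -0.03 at 24 h, 0.55 at 48 h and 0.26 at 72 h. The mutation is not described in the sources used here, and reads over the whole gene do not show whether a transcript makes protein. Among the other PRC2 subunits, Ezh2 and Eed gave averaged differences of 0.13 (adjusted p = 0.580) and 0.16 (adjusted p = 0.338).

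The WT time course asked which genes these cells silence and switch on. By 72 h WT cells had shut down the pluripotency network and switched on retinoic acid, Hox and early lineage genes. The master regulator Pou5f1 (ENSMUSG00000024406, chromosome 17, 35506018 to 35510772) fell from 104 to 0.319 RPKM, and Nanog fell from 62.1 to 0.894 RPKM. Cyp26a1 (ENSMUSG00000024987), the enzyme that degrades retinoic acid, was at 0.0218 RPKM at 0 h and rose to 65.0 at 24 h and 28.7 at 72 h, and the receptor gene Rarb rose from 0.0255 to 8.84 RPKM by 72 h. The smooth-muscle genes Tagln and Acta2 rose from 0.440 to 164 RPKM and from 0.391 to 117 RPKM, and the keratins Krt8 and Krt18 reached 163 and 210 RPKM. "Rose" and "fell" over time here need the authors' mark, which 4392 genes carry as different between 0 and 72 h in WT cells. By scaled RPKM, 2631 of them were higher and 1761 lower at 72 h.

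Of the 36 measured pluripotency genes, 35 fell in WT cells (median change -3.41), with Fgf4, Esrrb, Tdgf1 and Nr0b1 among the 8 genes with the largest falls of all. All 20 measured Hox genes rose (median 1.75), and 25 of 28 retinoic acid response genes rose (median 2.81). Endoderm markers rose in 20 of 28 cases (median 1.86), mesoderm markers in 9 of 12 (2.01), trophoblast markers in 8 of 10 (1.98), fibroblast markers in 11 of 11 (1.66) and developmental transcription factors in 26 of 41 (1.15). The filter favoured genes that rose, since a gene under 1 RPKM at 0 h was kept only if another column reached 1 RPKM. Of the deposited genes it kept 20 of 37 Hox genes and 41 of 151 developmental transcription factors. It also kept 12 of 30 mesoderm and 11 of 20 fibroblast markers. The shares that rose hold for the kept genes alone, in both lines. Imprinted genes rose in 16 of 24 cases (median 2.02), led by Igf2 at 0.0947 and then 59.5 RPKM, and 4 of 7 cell-cycle inhibitors rose (median 2.05). Epithelial and adhesion genes rose in 10 of 21 cases, p53 targets in 8 of 23 and 2-cell-like genes, normally active in the earliest embryo, in 7 of 10. Of the formative and primed markers, 7 of 11 fell and 3 rose (median -1.55). Replication genes fell in 7 of 25 cases and mitosis genes in 2 of 21, with medians of -0.74 and -0.60. Among the chromatin lists, 5 of 11 PRC2 subunits fell and 1 rose, 4 of 20 PRC1 subunits fell and 6 rose, 4 of 18 H3K27 and H3K4 enzymes fell, and 4 of 10 DNA methylation enzymes fell and 2 rose. Neural markers split evenly, with 7 of 18 higher and 7 lower. Of the germline genes 1 of 15 rose and 4 fell (median -0.48, matched random lists -0.38 to 0.89). Of the remaining lists, 3 of 18 housekeeping genes rose and 1 fell, and 3 of 9 abundant structural RNAs fell. By the size of the change alone, 491 genes were at least 2-fold higher and 410 lower at 24 h, 1355 and 899 at 48 h, and 1756 and 1217 at 72 h, of 10860 genes kept. Counting error alone gave 96, 101 and 94 such genes in simulation. On the deposited scale 955 genes were at least 2-fold higher and 199 lower at 24 h, 2453 and 415 at 48 h, and 2978 and 553 at 72 h.

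The Suz12-KO time course asked the same of cells labelled as lacking Suz12, and most of the lists went the same way. Pou5f1 fell from 137 to 1.35 RPKM, Nanog fell from 77.0 to 1.15 RPKM, and Tdgf1, Fgf4 and Esrrb were again among the largest falls. Acta2, Tagln, Cyp26a1, Pmp22, Igf2, Gas1, Krt18 and Krt8 were the 8 genes with the largest rises in both lines, with Cyp26a1 at 82.6 RPKM and Acta2 at 164 RPKM at 72 h in Suz12-KO cells. All 20 Hox genes kept by the filter rose, 35 of 36 pluripotency genes fell (-3.33), and 22 of 28 retinoic acid response genes rose (2.82). Endoderm markers rose in 25 of 28 cases (median 2.81) and p53 targets in 15 of 23 (1.42). Of the germline genes 8 of 15 fell (-1.02), of the replication genes 12 of 25 (-0.95), of the mitosis genes 8 of 21 (-0.95) and of the PRC2 subunits 6 of 11 (-1.08). None of the 10 2-cell-like genes rose and 2 fell (median 0.08). Of the formative and primed markers 3 of 11 rose and 5 fell, with a median of -0.10 whose sign turned on the deposited scale. The authors' table marks 4858 genes in Suz12-KO cells, and by scaled RPKM 2879 of them were higher and 1979 lower at 72 h. At least 2-fold, 671 genes were higher and 586 lower at 24 h, 1277 and 989 at 48 h, and 1819 and 1494 at 72 h, against 62, 60 and 93 from counting error alone. On the deposited scale the counts were 1501 and 252, 2324 and 497, and 2672 and 857.

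The comparison of the responses bears on the series title's question, whether PRC2 is needed to silence genes or arrives after they are silenced. RNA does not measure the arrival of PRC2, and Suz12 RNA did not show loss of Suz12. The lines also differed in Hprt, with 6 reads over the WT columns and 3568 over the Suz12-KO columns. Loss of Suz12 cannot be told apart here from other differences between the lines. Silenced genes in WT cells (marked by the authors and at least 2-fold lower at 72 h) numbered 1111. Of these, 850 (76.5%, 95% Wilson interval 73.9 to 78.9) were also marked and lower in Suz12-KO cells. Of the 1111 genes, 1088 were below their 0 h level there. Their median change was -1.45 in WT cells and -1.36 in Suz12-KO cells. The WT figure is enlarged by choosing the genes on it. When the set was chosen on Suz12-KO cells, 867 of 1251 genes (69.3%) were also marked in WT cells, and the median changes were -1.47 in Suz12-KO cells and -1.23 in WT cells. The median level of the 1111 genes went from 4.11 to 1.38 RPKM in WT cells and from 4.42 to 1.55 RPKM in Suz12-KO cells. In 99 of them the fall was weaker by at least 1 log2 unit in Suz12-KO cells, and in 24 it was stronger. With the set chosen on Suz12-KO cells the fall was weaker in WT cells in 118 genes and stronger in 30, so this asymmetry went with the choice of the set. At 72 h 46 of the 1111 genes were at least 2-fold higher in Suz12-KO cells and 10 lower, and at 0 h 22 were higher and 64 lower. Choosing genes that were high at 0 h and low at 72 h in WT cells favours both of these directions. The counts therefore do not show weaker silencing in Suz12-KO cells. Of 1541 genes induced in WT cells, 1316 (85.4%, Wilson interval 83.5 to 87.1) were also marked and higher in Suz12-KO cells. The median changes of the 1541 genes were 1.59 in WT and 1.56 in Suz12-KO cells. Both Wilson intervals treat genes as independent and cover neither counting error nor the spread between cultures. Across genes, which are not independent replicates, the 72 h changes of the lines had a Pearson r of 0.836 and a slope of Suz12-KO on WT of 0.863. Over the 9765 protein-coding genes r was 0.906. Error in the WT changes lowers such a slope, so a slope under 1 does not show a weaker response in Suz12-KO cells. Both lists of authors' calls shared 2029 genes that rose, where 309.8 would be shared by independent lists, and 1183 that fell, where 142.5 would be.

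**Figure D1:**
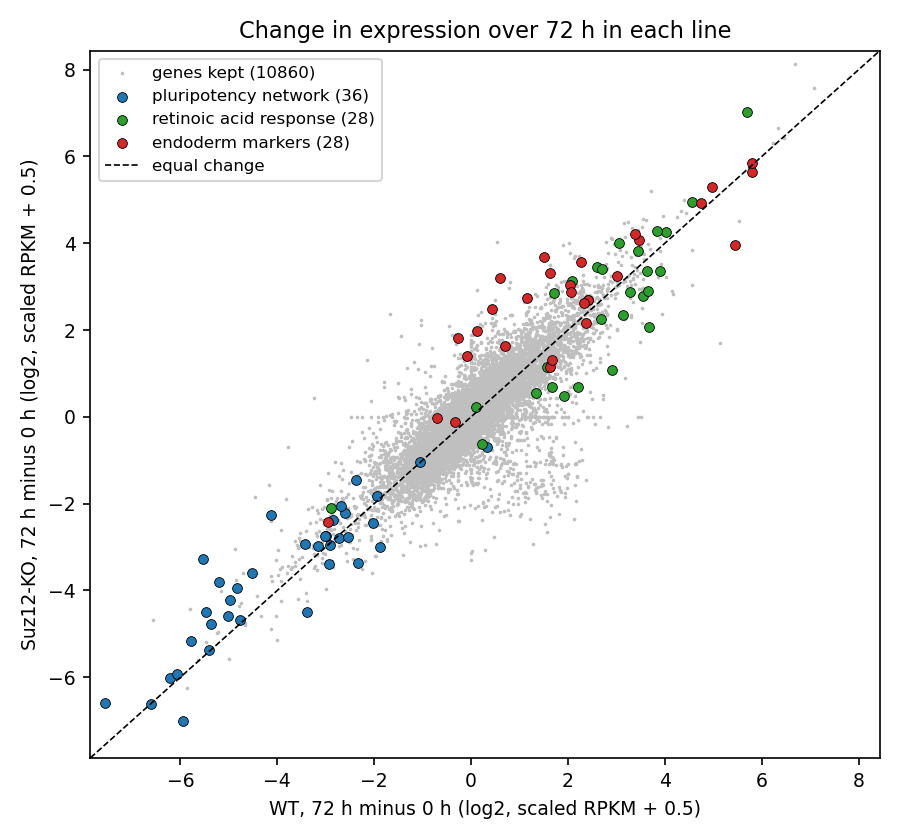
Change from 0 to 72 h in WT cells (x axis) and Suz12-KO cells (y axis), in log2 of scaled RPKM plus 0.5, for 10860 genes, each from 1 pooled column per group. Pluripotency genes lie at the lower left in both lines, and most endoderm markers lie above the dashed line of equal change.

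The Suz12-KO to WT contrast averaged over the 4 times asked which genes differed between the lines throughout. Col4a1 (ENSMUSG00000031502, chromosome 8, 11198423 to 11312826), a basement membrane collagen, was higher by 2.52 (SE 0.13, adjusted p = 7.65e-04, 4 of 4 times), with Col4a2 at 2.02 (adjusted p = 2.87e-03) and the laminin gene Lama1 at 2.63 (SE 0.32, adjusted p = 8.19e-03). Pmaip1 (ENSMUSG00000024521), which encodes the pro-apoptotic protein Noxa, was higher by 2.67 (SE 0.11, adjusted p = 2.25e-04), and Cdkn2a, a cell-cycle inhibitor and a classical Polycomb target, by 1.26 after scaling (SE 0.12, adjusted p = 6.54e-03). Hprt (ENSMUSG00000025630, chromosome X, 52988137 to 53021659), a purine salvage enzyme, was higher by 5.49 (SE 0.17, adjusted p = 1.62e-04), with 0 to 3 reads in each WT column and 16.1 to 34.7 RPKM in the Suz12-KO columns. Lower in Suz12-KO cells were Rian (ENSMUSG00000097451) at -4.29 (SE 0.27, adjusted p = 1.45e-03), the PRC1 subunit Cbx7 at -1.78 (SE 0.26, adjusted p = 0.0133) and the X-linked homeobox gene Rhox5 at -2.25 (SE 0.25, adjusted p = 7.00e-03).

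In all, 1308 genes passed limma at an adjusted p of 0.05, 1135 higher and 173 lower in Suz12-KO cells, from 1 column per line at each time. The p values measure how evenly a difference held over the 4 times, not the spread between cultures. On this scale the median gene was higher by 0.15. After scaling, 607 genes passed, 345 higher and 262 lower, and 507 genes passed on both scales. The endoderm regulators Gata4 (1.62, adjusted p = 0.0408) and Gata6 (1.13, adjusted p = 0.0409) passed on the deposited scale and not after scaling (adjusted p = 0.0656 and 0.0553). Without the 48 h columns 86 genes passed and without the 24 h columns 265, against 731 and 795 without the 0 h or 72 h columns.

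Of 24 lists tested with camera, which compares a list with all other genes, 10 passed at the preset correlation. Endoderm markers were higher (11 of 28 members passed over all genes and 14 adjusted over the list alone; adjusted p = 1.96e-03), as were p53 targets (7 of 23 and 12 adjusted over the list alone; adjusted p = 1.27e-03). Lower were 2-cell-like genes (median -0.99, 1 of 10 and 8 adjusted over the list alone; adjusted p = 5.66e-08), imprinted genes (5 of 24 lower and 4 higher, 11 and 8 adjusted over the list alone; adjusted p = 5.99e-04) and trophoblast markers (1 of 10 on either count; adjusted p = 1.27e-03). H3K27 and H3K4 enzymes, germline genes, PRC1 subunits, neural markers and abundant structural RNAs also passed as lower than other genes, with adjusted p between 0.0129 and 0.0423. The medians of the germline, PRC1 and neural lists were nonetheless slightly above 0 on the deposited scale (0.05, 0.04 and 0.00), because the median gene was above them. After scaling, the calls of endoderm markers, p53 targets, 2-cell-like genes and H3K27 and H3K4 enzymes passed and the other 6 did not, with adjusted p from 0.0615 for PRC1 subunits to 0.419 for neural markers and 0.0794 for imprinted genes and trophoblast markers. The members that passed over all genes were then 5 endoderm markers, 2 p53 targets, and 1 higher and 7 lower imprinted genes. None of the 10 calls held when the correlation between genes was estimated (adjusted p = 0.793 for each with an estimated correlation).

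At 0 h, before differentiation, the contrast showed the lines as they were in the undifferentiated state. Hprt stood at 30.1 RPKM in Suz12-KO cells and 0.0300 in WT cells. The collagen chaperone gene Serpinh1 (5.62 against 0.795 RPKM, log2 change 2.13) and the secretory pathway gene Kdelr3 (8.94 against 1.51, 2.07) were also higher in Suz12-KO cells, as were the epithelial genes Sfn (16.5 against 3.36) and Wfdc2 (8.61 against 1.53). Lower in Suz12-KO cells were the enolase gene Eno1b (0.439 against 16.2 RPKM), the germline gene Tdrd12 (2.34 against 10.0) and Rhox5 (2.61 against 12.3). Endoderm markers already had a median change of 0.24, above the middle 95% of random lists matched on expression (-0.14 to 0.10), and formative and primed markers were lower (median -0.58, range -0.22 to 0.21). Such ranges treat the genes of a list as independent and were not adjusted for the number of lists. DNA methylation enzymes (0.21, range -0.22 to 0.20) and mitosis genes (0.15, range -0.16 to 0.12) were slightly above their ranges. PRC1 subunits (-0.22), imprinted genes (-0.19) and trophoblast markers (-0.24) were below theirs, and their medians kept these signs under every scaling tried. Core pluripotency genes were close between the lines, with log2 differences of 0.13 for Pou5f1, 0.04 for Nanog and -0.03 for Sox2. At least 2-fold, 345 genes were higher and 233 lower in Suz12-KO cells, 119 of which counting error alone would give. Protein-coding genes made 144 and 100 of them, and short structural and regulatory RNAs (small nuclear, nucleolar, ribosomal and micro RNAs), 622 genes with a median change of 0.37, made 176 and 88. On the deposited scale 446 genes were higher and 140 lower.

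At 24 and 48 h the contrast followed the lines during differentiation. Col4a1 was at 6.02 against 0.785 RPKM at 24 h and at 34.1 against 5.37 RPKM at 48 h, and Gata4 at 0.777 against 0.0822 and at 2.19 against 0.0725 RPKM. The 2-cell-like gene AF067061 was at 0.133 RPKM in Suz12-KO cells and 4.09 RPKM in WT cells at 48 h. At 24 h 221 genes were at least 2-fold higher and 226 lower in Suz12-KO cells (protein-coding 173 and 95), with 65 from counting error alone, and on the deposited scale 422 were higher and 165 lower. At 48 h the counts were 183 and 325 (protein-coding 139 and 73), with 75 from counting error alone, and short structural and regulatory RNAs made 201 of the 325. On the deposited scale 297 genes were higher and 261 lower at 48 h, so the balance over all genes turned with the scaling.

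**Figure D2:**
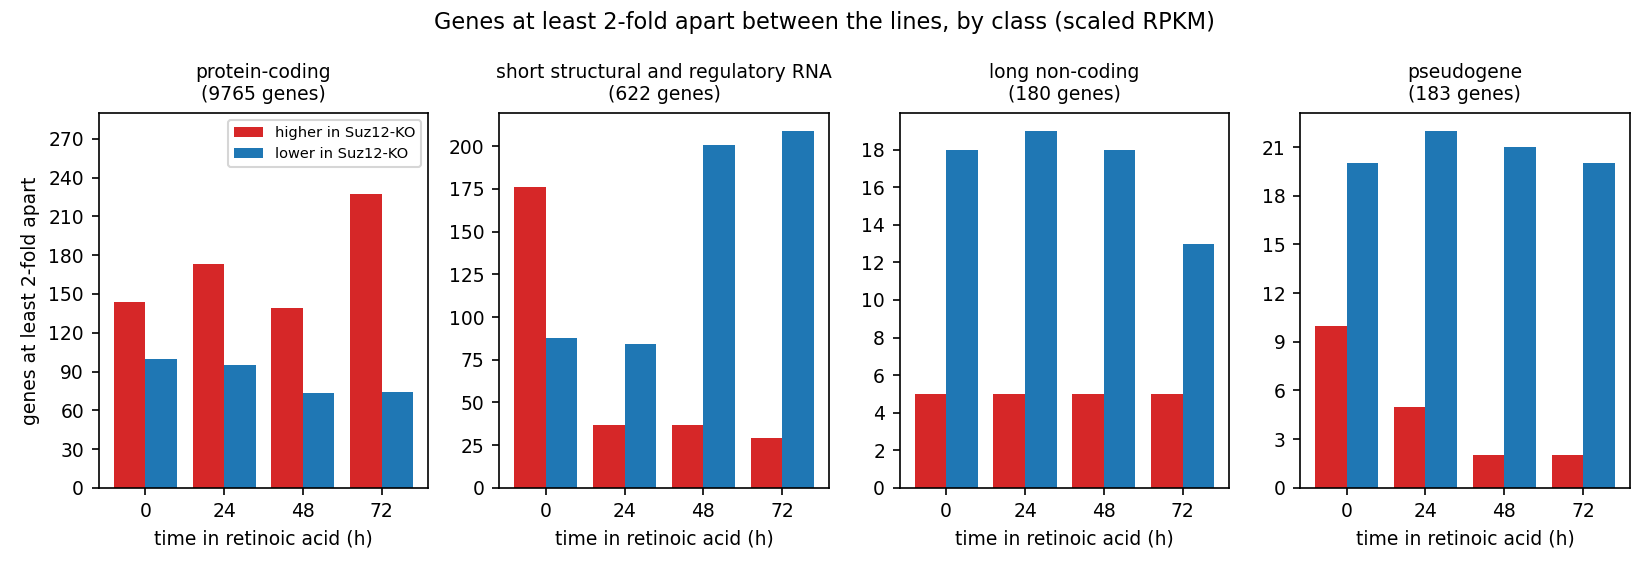
Numbers of genes at least 2-fold higher (red) or lower (blue) in Suz12-KO than in WT cells at each time, by annotated class, from scaled RPKM of 1 column per group. Among protein-coding genes more were higher than lower at every time, while short structural and regulatory RNAs went from 176 higher and 88 lower at 0 h to 29 higher and 209 lower at 72 h.

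At 72 h the contrast asked what the lines had become after the same treatment, and most endoderm markers were higher in Suz12-KO cells. Of the 28 endoderm markers, 24 were above 0 and 13 at least 2-fold higher (median 0.67, matched random lists -0.15 to 0.16). Lama1 (ENSMUSG00000032796, chromosome 17, 67697259 to 67822647) stood at 55.9 RPKM (55.0 to 56.9) against 4.67 (4.41 to 4.95), Col4a1 at 71.7 (70.5 to 73.0) against 8.78 (8.35 to 9.22), and Cubn, an endocytic receptor of visceral endoderm, at 8.38 against 0.346 RPKM. Gata4 was at 4.58 against 0.310 RPKM, Sox7 at 2.08 against 0.0574, Sox17 at 4.87 against 0.648 and Gata6 at 3.44 against 2.23. The lysosomal protease gene Lgmn stood at 53.7 against 6.64 RPKM and the calcium-binding protein gene S100g at 10.2 RPKM against 0.237, the latter from 3 reads.

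All 23 p53 targets were higher in Suz12-KO cells at 72 h (median 0.64, matched random lists -0.16 to 0.18), 6 of them at least 2-fold. The random range ignores correlation between members and is too narrow for this list and for the 2-cell-like genes below. Their correlations were estimated at 0.60 and 0.78 in the averaged fit. Estimates of 0.12 to 0.33 for the endoderm, pluripotency, epithelial, germline, PRC1 and imprinted lists make their ranges too narrow as well. Pmaip1 was at 7.79 against 0.672 RPKM and the death receptor gene Tnfrsf10b at 21.7 against 9.33. Cdkn1a, the p53-induced cell-cycle inhibitor, was at 27.1 against 14.2 RPKM and is named here after its values were seen. The pluripotency network had a median of 0.31 (-0.14 to 0.11), with 27 of 36 members above 0, among them Pou5f1 at 1.35 against 0.319 RPKM, although both levels were far below those at 0 h. Epithelial and adhesion genes were higher too (0.31, range -0.18 to 0.17). Lower were 2-cell-like genes (10 of 10, median -0.98, range -0.36 to 0.45), germline genes (12 of 15, -0.43, range -0.24 to 0.27), PRC1 subunits (16 of 20, -0.24, range -0.18 to 0.17) and, by a narrow margin, imprinted genes (-0.18, range -0.18 to 0.14). The imprinted RNA H19 was at 1.25 RPKM against 22.8, and Peg10 at 54.3 against 311. Fibroblast markers had a median of 0.32, within their random range of -0.34 to 0.43, and retinoic acid response genes one of -0.13 (-0.15 to 0.13). At least 2-fold, 267 genes were higher and 327 lower, with 68 from counting error alone. Protein-coding genes made 227 and 74 of them. Short structural and regulatory RNAs, with a median of -0.60, made 29 and 209. On the deposited scale 331 genes were higher and 310 lower.

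**Figure D3:**
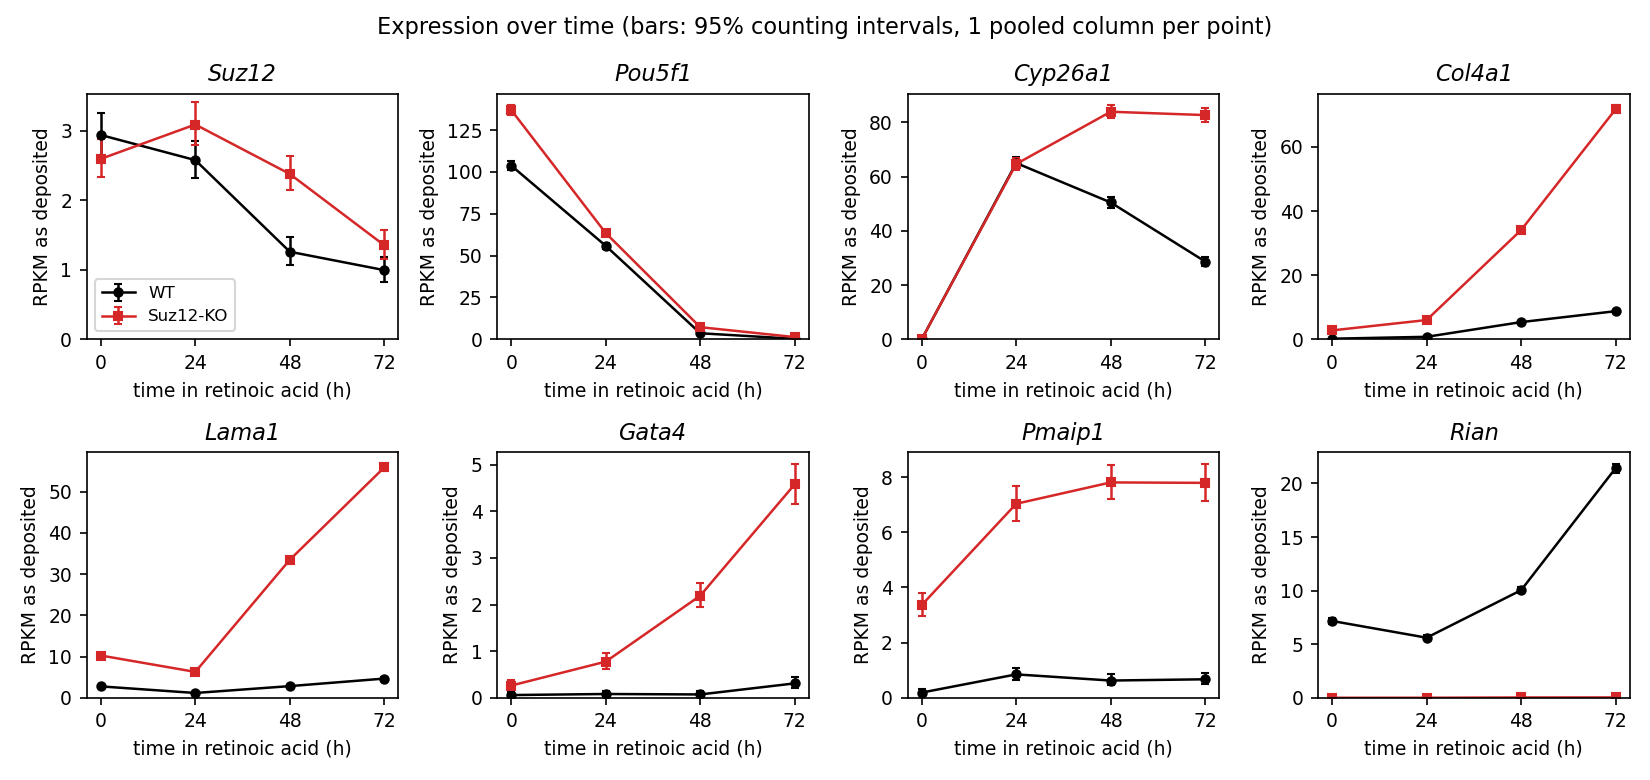
RPKM as deposited against time in retinoic acid for 8 genes in WT (black circles) and Suz12-KO cells (red squares), 1 pooled column per point, with 95% Poisson counting intervals. Suz12 RNA was not lower in the Suz12-KO columns after 0 h, Pou5f1 fell in both lines, and Col4a1, Lama1, Gata4 and Pmaip1 were higher in Suz12-KO cells.

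Genes that stood at least 4-fold apart in the same direction at all 4 times numbered 30, 5 higher and 25 lower in Suz12-KO cells. Of the 25 lower genes, 18 lay between Dlk1 and Dio3 on chromosome 12 (109463336 to 110279068), an imprinted domain whose long and short non-coding RNAs come from the maternal copy. Rian, its host gene for small nucleolar RNAs, stood at 7.17 RPKM in WT cells at 0 h and 21.4 at 72 h, against 0.00631 and 0.0385 RPKM in Suz12-KO cells. The small nucleolar RNA gene DQ267102 had 127 to 374 reads in each WT column and none in the Suz12-KO columns, a depth at which up to 1.65 RPKM at 72 h would go unseen against 196 RPKM in WT cells. Genes between Dlk1 and Dio3, leaving out Rtl1, had 30287 reads over the WT columns and 77 over the Suz12-KO columns. The protein-coding genes of the domain, made from the paternal copy and named after their values were seen, had no such deficit. Dlk1 stood at 13.1 RPKM in Suz12-KO cells and 6.75 in WT cells at 72 h, Rtl1 had 75 and 18 reads over the 4 times, and Dio3 had 62 and 71. The 5 higher genes were Hprt, Pmaip1, Col4a1 and the short RNA genes n-R5s136 and Gm25939. At the 2-fold level 24 genes were higher and 61 lower at all 4 times.

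**Figure D4:**
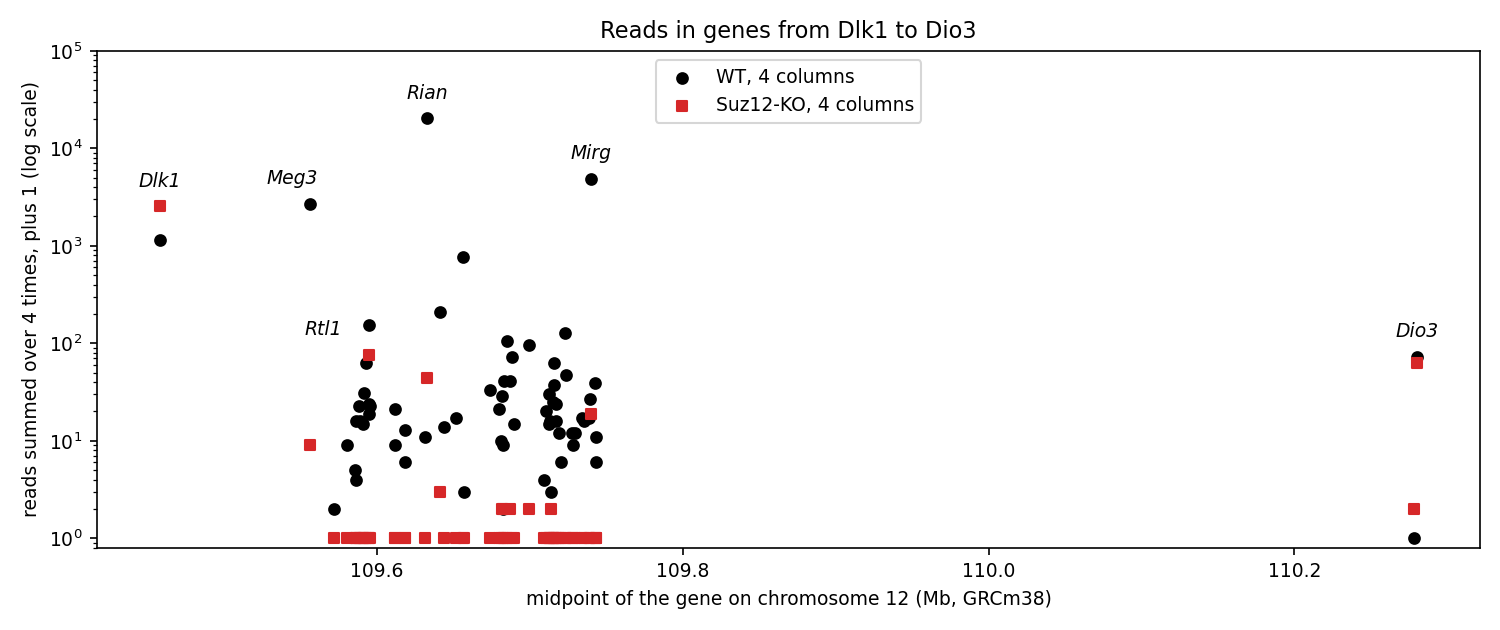
Reads summed over the 4 times, plus 1 (log axis), for each listed gene from Dlk1 to Dio3 on chromosome 12 (GRCm38), in WT (black circles) and Suz12-KO cells (red squares). Rian had 20211 reads in WT and 43 in Suz12-KO cells, whereas Dlk1 had 1148 and 2531.

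The difference between the responses asked which genes changed over 72 h to a different extent in Suz12-KO than in WT cells. Endoderm markers gained more in Suz12-KO cells, with 23 of 28 above 0 and a median difference of 0.64 (matched random lists -0.16 to 0.21), led by Cubn at 2.62. Lgmn rose from 4.94 to 53.7 RPKM in Suz12-KO cells and was at 3.92 and 6.64 RPKM in WT cells, a difference of 2.79. The matricellular gene Ccn2 rose from 2.54 to 16.4 RPKM in Suz12-KO cells and was at 3.60 and 3.91 RPKM in WT cells, and Spon2, which rose in both lines, gained more in Suz12-KO cells by 2.30. Fbxo15 and Tcea3 fell in both lines but less in Suz12-KO cells, by 2.24 and 2.60. For p53 targets 22 of 23 differences were above 0, with a median of 0.72 (-0.16 to 0.23). Formative and primed markers (0.45, range -0.34 to 0.39), mesoderm markers (0.38, range -0.33 to 0.38) and the pluripotency network (0.22, range -0.14 to 0.17) were also above their ranges, while 2-cell-like genes (-0.71), germline genes (-0.53), mitosis genes (-0.28) and replication genes (-0.20) were below theirs. The ranges are too narrow where members are correlated, as for p53 targets, 2-cell-like, mitosis and replication genes. Correlations between their members were estimated at 0.60, 0.78, 0.70 and 0.65 in the averaged fit. Estimates were 0.33 for germline genes, 0.19 for endoderm markers and 0.12 for the pluripotency network, whose ranges are too narrow as well. Retinoic acid response genes had a median of -0.34 (-0.16 to 0.19), with 13 members above 0 and 15 below. Stra8, a retinoic acid target that licenses meiosis, peaked at 80.8 RPKM in WT and 43.7 RPKM in Suz12-KO cells at 24 h and differed by -1.60 at 72 h, and Hoxb1 stood at 5.89 and 2.06 RPKM at 48 h, whereas Cyp26a1 was higher in Suz12-KO cells at 72 h (82.6 against 28.7 RPKM). The germline regulator Sohlh2 (-2.58) and Tex19.1 (-1.99) were among the 8 named genes with the most negative differences, led by the short RNA gene Vaultrc5 (-3.82). Hox genes (-0.10) and PRC2 subunits (0.02) lay within their ranges, and the sign of the PRC2 median turned on the deposited scale.

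Differences of at least 2-fold between the 72 h responses numbered 399 in the positive and 515 in the negative direction, against 173 and 332 at 24 h and 248 and 477 at 48 h. Among protein-coding genes the 72 h counts were 318 and 168, and over all genes on the deposited scale the counts were 191 and 310 at 24 h, 220 and 482 at 48 h, and 288 and 616 at 72 h. Short structural and regulatory RNAs made 302 of the 515 negative ones, their median going up by 0.51 in WT cells and standing at -0.59 in Suz12-KO cells. With 1 column per group the differences at a single time leave no residual degrees of freedom and were not tested, nor was a trend over time, and each line is a single clone or population by its label.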

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

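All tests in this part were chosen after the result was seen, except the test of gene length for the endoderm markers and the simulation of counting error for the short RNA genes.

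Of the genes that the authors' deposited table marks in both lines, 8 changed in opposite directions by scaled RPKM, and the differences were not tested. The Suz12-KO minus WT response was 2.43 for Ldhb, 2.39 for Pdgfb, 2.21 for Fam167a and 1.38 for Islr2. It was -0.86 for Entpd3, -1.95 for Ulbp1, -2.90 for n-R5s211 and -4.11 for n-R5s64. Ldhb went from 32.4 to 21.9 RPKM in WT cells and from 14.5 to 47.5 RPKM in Suz12-KO cells. Pdgfb, Fam167a, Islr2, Entpd3 and Ulbp1 did not exceed 1.84 RPKM at 0 or 72 h in either line. The log2 values of these 5 genes depend strongly on the added 0.5. Genes at least 2-fold higher at 0 h and at least 2-fold lower at 72 h in Suz12-KO cells numbered 88, and 7 genes went the other way, also without a test of the difference.

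Of the 30 genes at least 4-fold apart at all 4 times, 5 were higher and 25 lower in Suz12-KO cells. Direct derepression by loss of Suz12 as the whole cause would need most of them to be higher. The 18 lower genes between Dlk1 and Dio3 were low together and are not separate cases. Outside that domain 5 genes were higher and 7 lower, the latter including the pseudogenes Eif3s6-ps2, Gm12245 and Rpl3-ps1. These few genes argue against derepression as the whole cause, less strongly than the full count. Loss of the maternal non-coding RNAs of the Dlk1 to Dio3 domain is a candidate explanation for 18 of the 25 lower genes, since the paternally expressed genes kept reads in Suz12-KO cells, Dlk1 and Rtl1 with more than in WT cells and Dio3 with 62 against 71. A different parental line behind the KO columns is also a candidate explanation, since Hprt, which the widely used E14 derivative E14Tg2a is known to lack, had 6 reads over the WT columns and 3568 over the Suz12-KO columns. Whether loss of Suz12 or the history of the line led to the loss in this domain stays open.

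Endoderm markers had a median Suz12-KO minus WT difference of 0.67 at 72 h. Gene length was argued against, because the median lay at percentile 100 of random lists matched on expression and length (-0.13 to 0.15). Fibroblast or feeder cells were not excluded, since the fibroblast list median of 0.32 lay within its random range with members above and below 0, among them Col3a1 (5.06 against 3.76 RPKM) and Col1a2 (0.619 against 1.15 RPKM). A larger 72 h response to retinoic acid as the whole cause was argued against by that list's median response difference of -0.34. It lay below its random range and below that of the endoderm markers by 0.98, with an SD over members of 0.91. Single members such as Cyp26a1 (82.6 against 28.7 RPKM) were higher. This measure was chosen after the list's median Suz12-KO minus WT difference at 72 h (-0.13) had decided nothing. Averaged over the 4 times, the list's median Suz12-KO minus WT difference was 0.16, above its random range (-0.10 to 0.09). A stronger response at earlier times therefore stays open. Loss of Suz12 and a difference between the lines in their readiness to form endoderm also stay open and may act together.

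Of the 88 genes higher at 0 h and lower at 72 h in Suz12-KO cells, 84 (95.5%) were short structural or regulatory RNA genes and 0 were protein-coding. Counting error was argued against, as it gave 6.15 such genes on average over 20 simulations. A different recovery of short RNAs between libraries is a candidate explanation, since the 622 genes of this class had medians of 0.37 at 0 h and -0.60 at 72 h. A change of these RNAs in the cells was not tested and stays open.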

How the results depend on the processing

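Chosen after the data were seen were RPKM as deposited for single columns, protein-coding genes alone, leaving out each time and the test of other assignments of the columns. No paired analysis was possible because the columns carry no replicate number, which concerns pairing by replicate alone, since the averaged contrast has time as a block. A replicate block, a fit to the compared groups alone and leaving out single replicates were not run, because each column pools its group, and count-based tests were not run on RPKM. No call of a named gene, and no list median outside its random range, changed direction under the settings tried. Directions of other called genes and of camera calls were not compared. Suz12 kept its side of the threshold in all settings. Medians near 0 of several lists, such as the PRC2 subunits and the housekeeping genes, changed sign with RPKM as deposited or quantile normalization. The averaged medians of germline genes and PRC1 subunits, which passed camera as lower, were 0.05 and 0.04 as deposited and -0.13 and -0.13 after scaling. Of 153 counts and shares recomputed 61 moved, of 480 list medians 69 moved, of 556 changes of named genes between columns 83 moved, and of 1503 averaged changes of named genes 182 were weaker and 53 stronger. Except where fewer genes or columns were used, the cause was not tested. Genes with few reads limit what the smaller differences can show.

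For genes at least 2-fold apart, a pseudocount of 0.1 gave 949, 830, 818 and 958 for Suz12-KO minus WT at 0, 24, 48 and 72 h, 1648 and 2028 for 24 h minus 0 h in WT and Suz12-KO cells, and 879, 1103 and 1456 for the differences between responses. A pseudocount of 1 gave 261 for Suz12-KO minus WT at 24 h and 552 and 806 for 24 h minus 0 h in WT and Suz12-KO cells. A minimum of 5 RPKM, which tests fewer genes, gave 287, 222, 268 and 304, then 439, 1090 and 1419 for WT, 662, 1160 and 1617 for Suz12-KO cells, and 260, 360 and 446 for the differences between responses. No filter gave 801 for the difference between responses at 24 h. Protein-coding genes alone gave 244, 268, 212 and 301, and 149, 298 and 486 for the differences between responses.

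For the averaged contrast (1308 genes), no filter gave 336 genes, median-of-ratios scaling 607, quantile normalization 593 and a log2 fold change of at least 1 gave 202. Without the 0, 24, 48 or 72 h columns it gave 731, 265, 86 and 795 genes. Of the 8 assignments of the columns that keep times paired, 1 gave as many genes as the real one with 1308, and the highest other gave 0, but 8 are too few for a share under 0.05. For gene lists past camera (10), a minimum of 5 RPKM gave 2, median-of-ratios scaling 4, quantile normalization 4 and an estimated correlation 0. Fry was run on scaled RPKM, where camera gave 4, and gave 1 in one direction and 19 in either direction. The list past fry in one direction was H3K27 and H3K4 enzymes (lower, fry adjusted p = 0.0134). Endoderm markers (0.0858), 2-cell-like genes (0.175) and p53 targets (0.226) did not pass fry in one direction.

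The share of silenced genes also marked in the other line (76.5%) was 69.3% with the set chosen on Suz12-KO cells, 87.7% with RPKM as deposited, and 73.6% and 79.2% with pseudocounts of 0.1 and 1. The share of induced genes (85.4%) was 80.2%, 80.6%, 80.7% and 88.0% in the same order, and 87.8% for protein-coding genes. The correlation across genes of the 72 h responses (0.836) was 0.827 with RPKM as deposited, 0.802 with no filter, 0.862 with a minimum of 5 RPKM, 0.830 with quantile normalization and 0.906 for protein-coding genes.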

Other observations

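The genes described in this paragraph were chosen after their values were seen, and both hypothesis tests that follow were set down before their results were seen. Olig2, a neural lineage transcription factor, stood at 4.19 RPKM in Suz12-KO cells at 0 h and had 0 reads in WT cells, where up to 0.0477 RPKM would go unseen, and it stood at 0.0649 RPKM in Suz12-KO cells at 72 h. Its neighbour Olig1 went from 3.64 to 0.0547 RPKM in Suz12-KO cells. The list of developmental transcription factors as a whole had a median Suz12-KO minus WT change of 0.00 at 0 h, with 16 members above and 19 below 0, and 3 of 41 at least 2-fold higher and 1 lower.

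A hypothesis was that genes silent in WT cells at 0 h and higher in Suz12-KO cells carry the CpG-rich 5' ends typical of Polycomb targets. It was tested on 86 protein-coding genes under 1 RPKM in WT cells and at least 2-fold higher in Suz12-KO cells, 85 of them with a sequence. The random sets were drawn from 3092 protein-coding genes under 1 RPKM in WT cells at 0 h that reached 1 RPKM in another column. The median CpG ratio of the 85 genes over the first 500 nt of the transcript was 0.657. This was at percentile 50.1 of matched random sets (0.587 to 0.727), so no enrichment over that background was seen. Genes silent in every column were left out, so enrichment over all silent genes was not tested.

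Another hypothesis was that silenced genes with CpG-rich 5' ends are silenced less in Suz12-KO cells than CpG-poor ones. Over 626 CpG-rich (ratio of at least 0.6) and 391 CpG-poor genes, the difference in the median Suz12-KO minus WT response was -0.0311 (bootstrap 95% interval -0.12 to 0.06), at percentile 17.3 of 10000 random splits. The medians were 0.17 and 0.20, so no weaker silencing of CpG-rich genes was seen.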
